A study of Mus musculus with 2 samples.

How the data were processed

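The series holds 2 single-cell RNA libraries, 1 from sorted lung cells labelled WT and 1 from such cells labelled IP-/- (IPKO), both of male mice. Per the labels' protocols, EpCAM-positive cells negative for CD31, CD34, CD45, CD24 and Sca-1 were sorted by flow cytometry, libraries were made with the 10x Genomics Chromium Single Cell 3' kit, version v3.1, and they were sequenced on an Illumina NovaSeq 6000. This kit counts molecules by a tag near the 3' end of each transcript, so it reports on the end of a gene and not on a part deleted elsewhere in it. The deposited values are raw UMI counts per gene and barcode, made with Cell Ranger 4.0.0 per the file headers and per the submitters' processing notes. The genome build was GRCm38 (mm10) per the submitters' processing notes, while the annotation release is not given in the sources used here. The deposited count matrices hold called barcodes only, with a lowest total of 500 UMIs, and droplets without cells were not used here, so free RNA was not measured directly. Gene positions come from the GENCODE vM21 annotation of GRCm38, in which 27722 of the 27998 features (99.0%) were found by gene ID.

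The groups follow the genotype label, with 1 library each. The comparisons, filters, clustering settings, gene lists, cell type markers, the rule for named genes and 33 alternatives were fixed before the data were examined. The rule by which clusters were named from these markers and 7 alternatives were set afterwards. Barcodes with under 500 genes (1911 labelled WT, 1682 labelled IPKO) or over 20% mitochondrial UMIs (2055 and 1725) were removed. Scrublet, run per library through scanpy 1.11.5, called 1 and 2 doublets (0.0148% and 0.0248% of cells), which means that it did not work here; removing the highest 8% of its scores per library was added as an alternative. The kept 6744 and 8070 cells held 124207593 and 134955613 UMIs, with medians of 3350 and 3298 genes. AT2-like cells held 101837668 and 124852798 of these UMIs, so that counting error is small for most genes in them, while classes of few cells are limited by it.

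Cells of both libraries were clustered together without integration: counts were scaled to 10000 per cell and log-transformed, 2000 variable genes gave 30 principal components, and a graph of 15 neighbours was divided by the Leiden method (igraph 0.11.9) at resolution 0.5. Leading genes of a cluster were ranked by fold over all other cells (CPM plus 5), among genes detected in at least 20% of its cells. A cluster was named after a cell type when at least 3 of its 10 leading genes were fixed markers of that type and no other type tied. With no such type it was called AT2-like if its median AT2 marker reached at least 50% of its level over all cells, and low-RNA if at least 5 of its 20 leading genes were mitochondrial. Because AT2 genes are in all cells of such a sort, AT2-like clusters rest on that level and not on their leading genes, which included heat shock, early response and antigen presentation genes. Small clusters of other cells were divided again at resolution 1.0, a setting chosen after seeing the data. Transitional-like, endothelial-like and low-RNA cells were compared only as such classes.

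Counts were summed over the cells of a class in each library and given as CPM of those cells. Ratios are the library labelled IPKO over the library labelled WT, on the log2 scale, with exact conditional binomial intervals. Single levels have exact Poisson intervals and shares exact Clopper-Pearson intervals, all at 95%. A level with 0 UMIs was set at a floor of 3 counts. With 1 library per group no test between groups was possible and none was made. Named genes were Ptgir, Jun, Trp53, Cdkn1a, Mdm2, Krt8 and Sftpc, and the 12 highest and 12 lowest ratios among genes with a mean of at least 20 CPM, leaving out mitochondrial, ribosomal protein, haemoglobin and unnamed gene models and AY036118, and up to 4 members of each list, the 2 highest and the 2 lowest ratios; in contrasts between states up to 4 members per list were named likewise. The value of 1 gene near Ptgir is not reported here.

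The 27 gene lists covered surfactant and AT2 identity, AT1 differentiation, the AT2 to AT1 transitional state, AP-1 and immediate early genes, p53 targets, cAMP and CREB response, prostanoid synthesis and receptors, S phase, G2/M phase, senescence, fatty acid and sterol synthesis, inflammatory and NF-kB response, interferon response, MHC class II, MHC class I, TGF-beta and matrix, YAP and TAZ targets, Wnt targets, the Notch pathway, unfolded protein and integrated stress response, heat shock, hypoxia and glycolysis, oxidative phosphorylation, apoptosis regulators, NRF2 targets, ribosomal proteins and mitochondrially encoded genes. They were written from general knowledge and not from these libraries, and 533 of their 535 entries matched a gene name in the files. A list is given by the median log2 ratio of its members with a mean of at least 5 CPM, a counting interval from 1000 Poisson draws, and the percentile of the median among 10000 random lists of the same size matched on expression in 20 bins. A member was counted as higher or lower when it differed by a log2 of at least 0.32 with an interval that leaves out no difference. Lists share some genes, such as Areg, Atf3, Fosb and Cdkn1a. Shares of cells with a UMI were taken after thinning each cell to 3000 UMIs.

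The ratio and list functions were tested on simulated data drawn for the comparison of AT2-like cells over 8465 genes, of which 50 each were changed by a log2 of 0.32, and 1.5, 2 and 4-fold. At the limit for counting a member as higher or lower, 38% of the genes changed by a log2 of 0.32 were found. All genes changed 1.5-fold or more were found, and 0% of the unchanged genes. The intervals held the true value for 95.2% of genes, and 3% of unchanged lists fell outside the middle 95% of random lists. The simulated sums were independent Poisson counts, the model behind the intervals, without variation between cells, animals or libraries. These rates thus check the functions and do not measure errors from such variation. Alternatives covered TMM factors (edgeR 4.0.16 in R 4.3.3) and median-of-ratios factors, the total without the 20 genes with the most UMIs, all kept cells, within-cell means, thinning, other filters, resolutions, components and list minimums, and each library clustered alone. Other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and figures were drawn with matplotlib 3.10.9.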

Results

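Gene expression was measured in single cells sorted from the lungs of male mice by flow cytometry, as EpCAM-positive cells negative for CD31, CD34, CD45, CD24 and Sca-1, which the submitters call alveolar type 2 (AT2) cells. AT2 cells make surfactant and can give rise to the flat alveolar type 1 (AT1) cells of the gas exchange surface. One library is labelled wild type (WT) and 1 is labelled IP-/- (IPKO), that is, lacking the prostaglandin I2 receptor, which is encoded by Ptgir. The series title ties the activation of this receptor to alveolar regeneration through JUN and p53, so the comparison asks how AT2 cells without the receptor differ from wild-type cells, and where genes related to JUN and p53 stand. The labels state no injury or treatment. The library labelled WT held 8924 barcodes with 127287281 unique molecular identifiers (UMIs), and the library labelled IPKO held 10014 barcodes with 137471506 UMIs. After filtering, 6744 cells labelled WT (75.6% of barcodes, median 18056 UMIs) and 8070 cells labelled IPKO (80.6%, median 16664.5 UMIs) were kept. A mitochondrial share above 20% removed 23.03% of barcodes labelled WT and 17.2% of those labelled IPKO. With 1 library per genotype there are no replicates, no difference between the libraries was tested, and all intervals are 95% intervals that cover counting error only.

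Ptgir went against the labels. In AT2-like cells its UMIs were found in the library labelled IPKO and not in the library labelled WT: 292 UMIs in 277 of 7043 cells (3.93%, exact interval 3.49% to 4.41%) against 0 UMIs in 5266 cells. The level labelled IPKO was 2.34 UMIs per 1000000 UMIs of those cells (CPM; exact Poisson interval 2.08 to 2.62). The 0 UMIs labelled WT, among 101837668, have an exact upper limit of 0.0362 CPM (0.0295 CPM at the floor of 3 counts), and the exact interval of the ratio starts at a 64.2-fold higher level in the library labelled IPKO. Over all kept cells the counts were 1 UMI labelled WT, in a mesenchymal-like cell, and 328 UMIs labelled IPKO. This 1 UMI gave 1.93 CPM (0.0488 to 10.7) in the pooled endothelial-like, mesenchymal-like and immune cells labelled WT. That interval overlaps the interval of this pool labelled IPKO given next, so no difference is shown in these cells. Within the library labelled IPKO, Ptgir stood at 3.13 CPM (1.75 to 5.17) in transitional-like cells and at 7.37 CPM (3.18 to 14.5) in the pooled endothelial-like, mesenchymal-like and immune cells, the latter from 8 UMIs in 183 cells; with the 90 unnamed cells this pool stood at 5.95 CPM. Ptgir (ENSMUSG00000043017) lies on chromosome 7 from 16906490 to 16910905 (GRCm38, plus strand) and overlaps no other annotated gene. Which part of the gene was removed is not given in the sources used here, and a 3' tag outside a deleted part checks nothing, so the UMIs labelled IPKO do not by themselves contradict a deletion. Directions are therefore given between the library labelled WT and the library labelled IPKO, not between genotypes.

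**Figure D1:**
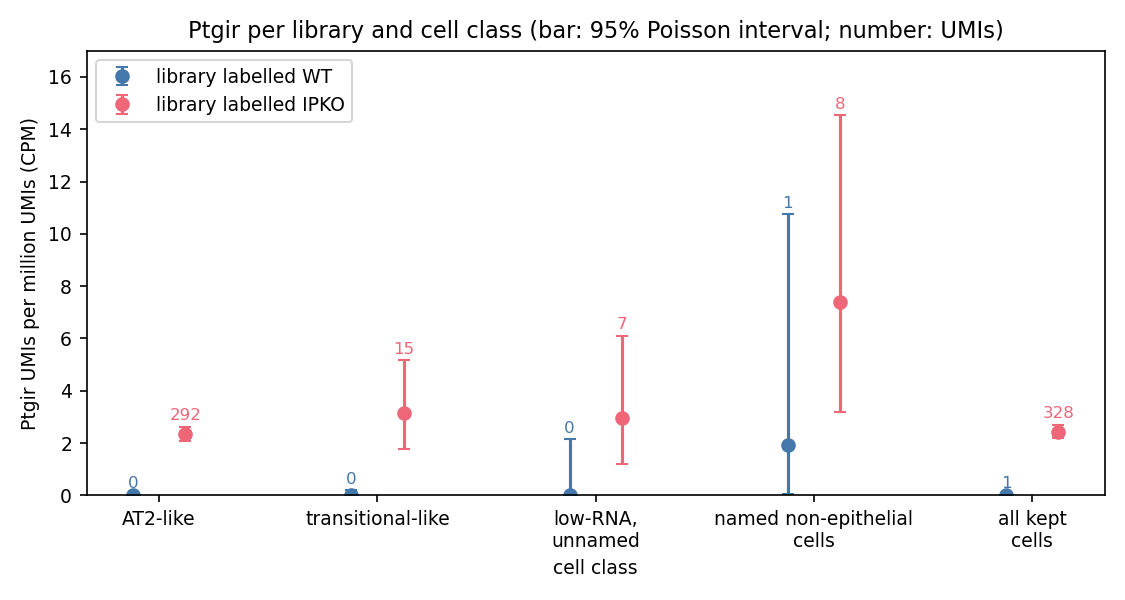
Ptgir level (CPM, y axis) in 4 cell classes and in all kept cells (x axis) of the library labelled WT (blue) and the library labelled IPKO (red); points are pooled levels, bars 95% Poisson intervals, and numbers the UMIs behind each point. AT2-like cells held 0 Ptgir UMIs in the library labelled WT and 292 in the library labelled IPKO.

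Genes around Ptgir also differed. Pnmal2, the gene on the far side of the calmodulin gene Calm3 and 33.8 kb from Ptgir (chromosome 7, 16944682 to 16948828), had 2 UMIs labelled WT and 448 labelled IPKO in AT2-like cells (log2 ratio 7.51, interval 5.65 to 10.56). Its neighbour Pnmal1 had 0 and 12 UMIs. Calm3 itself, next to Ptgir, had a log2 ratio of 0.26, and Strn4, Prkd2 and Ppp5c, also within 100 kb and with at least 1 CPM, had ratios of -0.11, 0.13 and -0.12. Within 10 Mb of Ptgir, 13 of 89 measured genes (14.6%, exact interval 8.01% to 23.7%) differed at least 1.5-fold between the libraries. Elsewhere 296 of 8373 genes (3.54%) did. This interval counts genes, taken as independent, and does not cover the counting error of UMIs. The 13 included Pglyrp1, which encodes a peptidoglycan recognition protein (4.24), Fosb (1.32), the glutamine transporter gene Slc1a5 (-1.07) and Cyp2b10, a cytochrome P450 gene (-5.00). Pnmal2, Pnmal1, Pglyrp1 and Slc1a5 were chosen for mention after their values were seen.

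**Figure D2:**
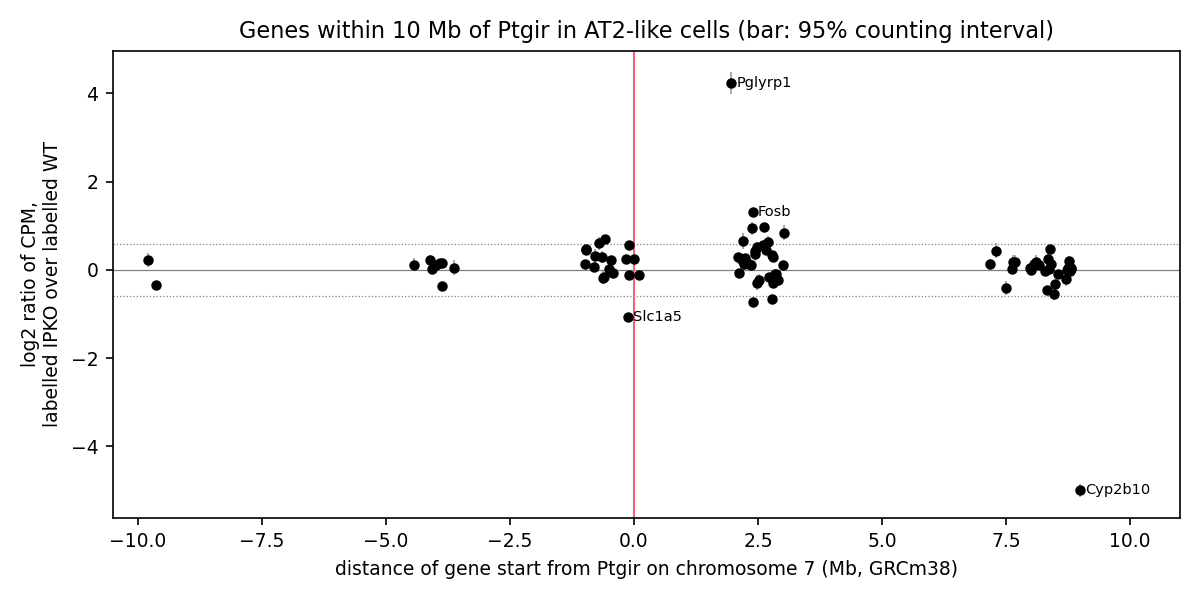
Log2 ratio of CPM, library labelled IPKO over library labelled WT (y axis), for genes with a mean of at least 5 CPM in AT2-like cells against the distance of the gene start from Ptgir on chromosome 7 in Mb (x axis, red line at Ptgir); bars are 95% counting intervals, dotted lines mark 1.5-fold, and genes at 2-fold or more are named. Of the 89 genes shown, 13 differed at least 1.5-fold, from Cyp2b10 at -5.00 to Pglyrp1 at 4.24.

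The cells were nearly all of the AT2 lineage in both libraries. AT2-like cells made up 78.1% of kept cells labelled WT (5266 cells) and 87.3% of those labelled IPKO (7043 cells). The order of these shares depended on the settings, so no direction is drawn from it. In the same order they were 85.5% and 74.0% with each library clustered alone and 92.8% and 90% at resolution 0.3. With doublets kept they were 71.7% and 84.4%. No cluster was AT1-like. The AT2-like cells did not mix: cluster 0, led by Cyp2b10, Chil1, Nr1d1 and Mfsd2a, held 5209 cells labelled WT and 109 labelled IPKO, while cluster 7, led by Hspa1a, Hspa1b, Egr1, Atf3, Fosb and Jun (38 and 4549 cells), and cluster 3, led by Ifi27l2a, Lrg1 and H2-Q7 (19 and 2385 cells), were almost wholly labelled IPKO. Cells named as types the sort should exclude (endothelial, mesenchymal and immune) were 1.45% (98 cells) labelled WT and 2.27% (183 cells) labelled IPKO. With the 25 and 90 unnamed cells given below they numbered 123 and 273. Leading genes of those unnamed cells included the immune genes Cd79a, C1qa and Plac8 and the endothelial gene Vwf. Endothelial-like cells numbered 48 in each library. T and NK cell-like cells numbered 15 and 84, mesenchymal-like 19 and 26, macrophage and monocyte-like 10 and 15, neutrophil-like 6 and 10, ciliated-like 3 and 14, club and secretory-like 12 and 8, and cycling-like, a cluster that also carried the lymphocyte chemokine gene Ccl5 among its leading genes, 2 and 10. A low-RNA cluster with a median of 6095 UMIs and 12.9% mitochondrial UMIs (248 and 397 cells), a cluster of mixed AT2, immune and endothelial RNA (9 and 37) and other cells without enough markers (25 and 90) stayed unnamed.

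A transitional-like cluster, led by S100a6, Lgals3, Areg, Krt19 and Sfn, held 1081 cells labelled WT (16.0%, interval 15.2% to 16.9%) and 288 labelled IPKO (3.57%, 3.17% to 3.997%). A state marked by keratin genes is known from AT2 cells on their way to AT1 cells. After thinning to 3000 UMIs, Krt8 was in 48.5% of this cluster's cells labelled WT and 70.0% labelled IPKO. Cldn4, another marker of that state, was in 0.37% and 0.35%. The cluster's median AT2 marker stood at 97.8% of its level over all cells. The name thus rests on the leading genes. No direction is drawn from the shares of this cluster in the libraries. Several of the defining genes themselves differed between the libraries, and the order of the cluster's shares turned with the settings. With each library clustered alone the shares were 8.21% labelled WT and 17.2% labelled IPKO, and without the 309 genes that differ at least 1.5-fold they were 15.4% and 18.0%. Over 11 other settings the share labelled WT was higher in 5 and the share labelled IPKO in 6. Counted per cell over the union of AT2-like, transitional-like and low-RNA clusters, with no border between them, cells thinned to 3000 UMIs held a mean of 3.52 UMIs of the 20 transitional-state genes labelled WT (SD 5.09 over 6544 cells) and 3.63 labelled IPKO (SD 5.22 over 7654 cells), after 51 and 74 shallower cells were left out.

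**Figure D3:**
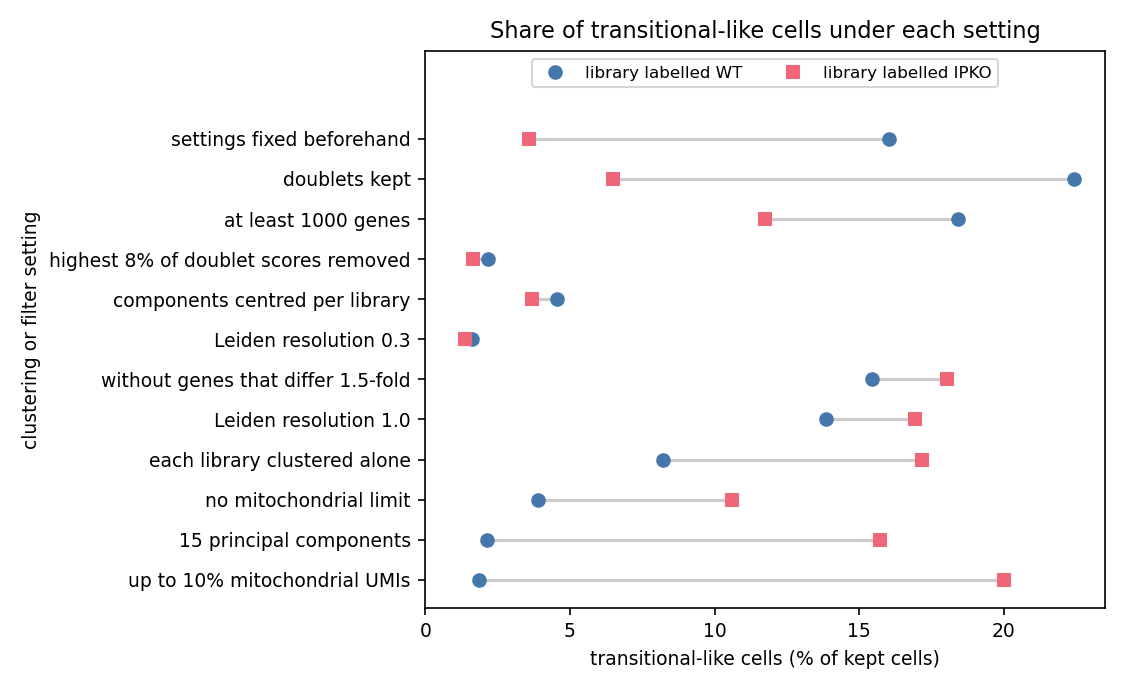
Transitional-like cells as a percentage of kept cells (x axis) in the library labelled WT (blue circles) and the library labelled IPKO (red squares) under the settings fixed beforehand and 11 others (y axis). The library labelled WT has the higher share in 5 of the 11 other settings and the library labelled IPKO in 6.

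In AT2-like cells, early response, heat shock and antigen presentation genes were higher in the library labelled IPKO, and the single genes with the lowest ratios included Nr1d1, Nr1d2, Chil1 and Scgb1a1. Hspa1a and Hspa1b, inducible HSP70 chaperones, had log2 ratios (labelled IPKO over labelled WT) of 2.84 (76.8 to 550 CPM) and 2.73, and their co-chaperone gene Dnajb1 1.76; the split of UMIs between the near-identical Hspa1a and Hspa1b is uncertain. The transcription factor gene Jun stood at 684 CPM labelled WT and 1441 CPM labelled IPKO, a log2 ratio of 1.07 (1.06 to 1.09). On the other side, Nr1d1 and Nr1d2, which encode the clock repressors REV-ERB alpha and beta, had log2 ratios of -4.35 (79.8 to 3.92 CPM) and -3.41, the chitinase-like gene Chil1 -2.32 and the club cell secretory gene Scgb1a1 -2.09. The surfactant gene Sftpc was level, at 213605 and 210694 CPM (-0.02). These AT2-like cells come from cluster 0 in the library labelled WT and from clusters 3 and 7 in the library labelled IPKO, so the values compare clusters as much as libraries. The difference in Scgb1a1 shrank to -0.29 with each library clustered alone, and in transitional-like cells the pooled level and the share of cells went opposite ways: 387 CPM labelled WT and 1563 CPM labelled IPKO, but 44.1% and 26.8% of cells with a UMI after thinning to 3000 UMIs.

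By the rule fixed for naming genes, the 12 highest ratios among genes with a mean of at least 20 CPM were, beside Hspa1a, Hspa1b and Dnajb1, those of the interferon-inducible gene Ifi27l2a (4.52, from 5.32 to 122 CPM), the transcription factor genes Klf2 (2.31), Atf3 (1.496), Ier2 (1.32), Fosb (1.32), Nr4a1 (1.32) and Egr1 (1.28), the EGF receptor ligand gene Areg (1.64) and Rasl11a (1.248). The 12 lowest were, beside Nr1d1, Nr1d2, Chil1 and Scgb1a1, those of Cyp2b10 (-5.00, from 114 to 3.57 CPM), Rgcc (-1.74), the lysophospholipid transporter gene Mfsd2a (-1.64), PISD on an unplaced scaffold (-1.36), the kinase gene Pim3 (-1.34), Ppp1r1b (-1.27), the protease inhibitor gene Spink5 (-1.22) and Il11ra1 (-1.11), which overlaps Galt on the same strand. Cyp2b10 and Fosb lie 8.99 Mb and 2.40 Mb from Ptgir, in the region with many differing genes. Areg, a marker of the transitional state, moved most with the choice of cells among the 12 highest, to 0.83 over all kept cells and 0.36 with each library clustered alone. Across 8465 genes with at least 5 CPM, the median log2 ratio was 0.08 and 85.1% of genes lay within 0.32 of 0.

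**Figure D4:**
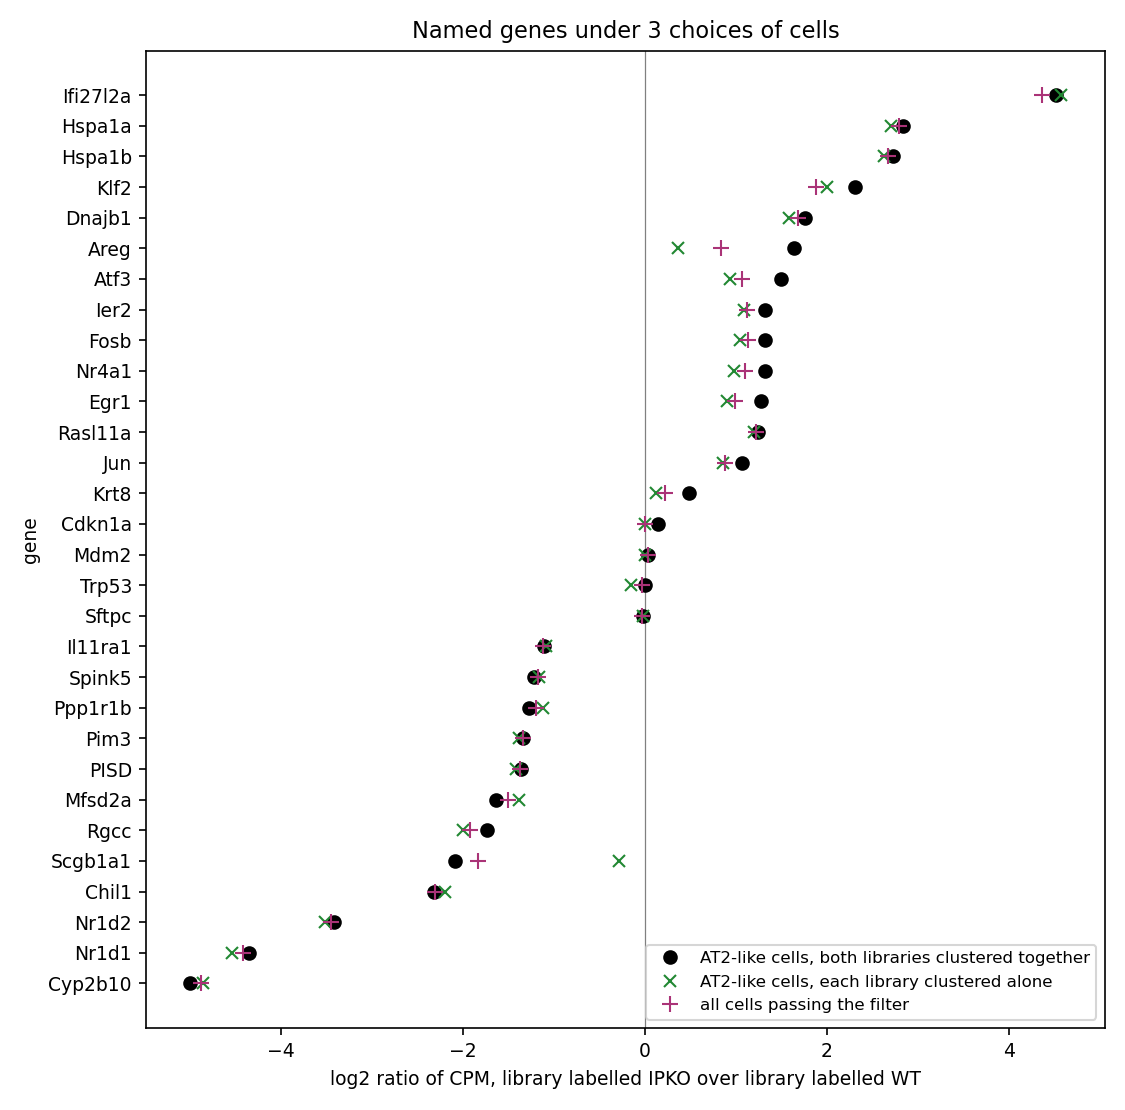
Log2 ratio of CPM, library labelled IPKO over library labelled WT (x axis), for the named genes with at least 5 CPM (y axis) in AT2-like cells of the joint clustering (black circles), in AT2-like cells with each library clustered alone (green crosses) and in all kept cells (purple plus signs). Hspa1a is at 2.84, 2.71 and 2.80, while Areg (1.64, 0.36 and 0.83) and Scgb1a1 (-2.09, -0.29 and -1.84) move.

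The AP-1 and immediate early list, which holds JUN and FOS family genes, had the highest median of the 27 lists under the settings fixed beforehand: 0.83 (counting interval 0.81 to 0.84) over 16 measured genes, above all 10000 random lists matched on expression, as a description of these libraries. Members are counted as higher or lower from a log2 difference of 0.32, and 12 were higher in the library labelled IPKO and 1 lower, with Atf3 at 1.496, Ier2 at 1.32, Maff at -0.46 and Fosl2 at -0.28. The median differed between the clusters labelled IPKO: against all AT2-like cells labelled WT it was 1.14 in cluster 7 and 0.11 in cluster 3. The rank depended on the settings: MHC class II genes stood above AP-1 genes over all kept cells (0.74 and 0.63) and with each library clustered alone (0.64 and 0.59). The cAMP and CREB response list, chosen because the receptor raises cAMP, had a median of 0.33 (7 of 14 genes higher, 3 lower), with Areg at 1.64 and Per2 at 1.34 and with Gem at -1.06 and Ppargc1a at -0.94. This median was 0.51 over all kept cells and ran from 0.24 to 0.82 over 13 other settings. Per1, Per2 and Nfil3 of the cAMP and CREB list are also among the clock genes given further below. The heat shock list had a median of 0.48, with 11 of 16 genes higher and none lower; its lowest member was Hspb8 at -0.07, and the mean over its members was 0.83.

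p53-related genes differed little in AT2-like cells. The p53 target list had a median of 0.09 (0.02 to 0.13; percentile 55.3), close to the median of all genes, with 2 of 17 genes higher (Plk2 at 1.39, Ddit4 at 0.65) and 2 lower (Sesn2 at -0.61, Trp53inp1 at -0.37). Its sign rests on the scaling, since median-of-ratios size factors gave -0.0018. Trp53, which encodes p53, had a log2 ratio of 0.01, its negative regulator gene Mdm2 0.03 and the cell cycle inhibitor gene Cdkn1a 0.15 (0.09 to 0.21), which became -0.0022 with each library clustered alone. Senescence-associated genes had a median of 0.29 (4 of 9 higher, none lower, with Bmp4 at 0.56 and Igfbp7 at 0.42), and of 0.18 over all kept cells. Apoptosis regulators stood at 0.09 (2 of 16 higher, Bik at 0.68 and Mcl1 at 0.59, none lower).

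Antigen presentation genes were higher in the library labelled IPKO. All 7 measured MHC class II genes were higher, with a median of 0.79 and with H2-Eb1 at 0.87, the invariant chain gene Cd74 at 0.83 and H2-DMb1 at 0.56. MHC class I and antigen processing genes had a median of 0.61, with 10 of 13 higher, H2-Q7 at 1.33 and H2-T23 at 0.95; the split of UMIs among near-identical class I genes is uncertain. Interferon response genes had a median of 0.43 (6 of 8 higher, none lower), with Ifitm3 at 1.78, Ifi27 at 1.06 and Irf1 at -0.02, and the median was 0.89 with members of at least 1 CPM. In contrast to AP-1, the MHC class II median was alike in both clusters labelled IPKO, at 0.70 in cluster 3 and 0.84 in cluster 7. Cluster 0 was the only AT2-like cluster with at least 100 cells of each library. Its 109 cells labelled IPKO, set there by their likeness to cells labelled WT, differed from the 5209 labelled WT by medians of -0.0024 for MHC class II genes, 0.26 for AP-1 genes (0.16 to 0.34) and -0.43 for unfolded protein response genes (-0.61 to -0.32). The inflammatory and NF-kB list stood at -0.09, with Nfkbiz at 1.08 and Relb at 0.63 higher and Lrg1 at -0.41 and Lcn2 at -0.37 lower.

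Of the lineage lists, transitional-state genes had a median of 0.51 in AT2-like cells (7 of 12 higher, none lower), with Areg at 1.64, S100a6 at 1.22, Krt8 at 0.49 and Clu at -0.25. This median depended on how transitional-like cells were set apart, since it was 0.10 over all kept cells and 0.05 with each library clustered alone. AT1 differentiation genes had a median of 0.19 (5 of 15 higher, none lower; Akap5 at 1.13, Hopx at 0.82, Lmo7 at -0.17), which was 0.094 over all kept cells and 0.049 with each library clustered alone. Surfactant and AT2 identity genes had a median of -0.10 (-0.11 to -0.09), with none of 19 higher and 2 lower, the desaturase gene Scd1 at -0.46 and the chemokine gene Cxcl15 at -0.35; Nkx2-1 stood at 0.25 and Lyz2 at 0.18.

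Mitochondrially encoded genes were lower in the library labelled IPKO, all 13 of them, with a median of -0.50, beside a median mitochondrial share of kept cells of 5.24% labelled WT and 3.91% labelled IPKO. Nuclear-encoded oxidative phosphorylation genes stood at 0.06 with none of 25 higher or lower. Unfolded protein and integrated stress response genes had a median of -0.32 (9 of 19 lower, 2 higher), with the chaperone cofactor gene Sdf2l1 at -1.58, Herpud1 at -0.98 and Calr at -0.87, and with Atf3 at 1.496 and Ppp1r15a at 0.41; with members of at least 20 CPM the median was -0.21. Fatty acid and sterol synthesis genes stood at 0.07 (1 of 23 higher, Pcyt1a at 0.58; 3 lower, among them the lipid droplet gene Plin2 at -0.64). The signs of the oxidative phosphorylation and fatty acid medians turned under both other size factors.

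The other lists had medians between -0.19 and 0.27. Prostanoid synthesis and receptor genes stood at -0.03 (1 of 6 higher, 2 lower), with the inducible cyclooxygenase gene Ptgs2 at 0.64, Ptges2 at 0.22, the prostaglandin E synthase gene Ptges at -0.97 and Ptgs1 at -0.33. Wnt targets stood at 0.27 (2 of 7 higher, Sp5 at 0.47 and Rnf43 at 0.46; Nkd1 at -0.32), Notch pathway genes at 0.16 (1 of 4 higher, Jag1 at 0.38), S phase genes at 0.16 (2 of 6 higher, Mcm4 at 0.35 and Pcna at 0.33), TGF-beta and matrix genes at 0.11 (2 of 15 higher, 1 lower; Thbs1 at 0.52, Tgfbi at -0.35) and ribosomal protein genes at 0.14 (none of 20 higher or lower). YAP and TAZ targets stood at 0.02 (1 of 12 higher, Cyr61 at 2.02; 3 lower, with F3 at -1.55), hypoxia and glycolysis genes at 0.01 (1 of 17 lower, Hk2 at -0.90) and NRF2 targets at -0.0012 (3 of 17 higher, with Gsta3 at 1.03; 1 lower, Gclc at -0.46). Over 13 other settings the medians ran from -0.045 to 0.31 for Wnt targets, from 0.068 to 0.27 for Notch pathway genes, from 0.0090 to 0.19 for S phase genes, from -0.039 to 0.17 for TGF-beta and matrix genes and from 0.056 to 0.16 for ribosomal protein genes. Only Bub1 of the G2/M list was measured, at -0.19.

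**Figure D5:**
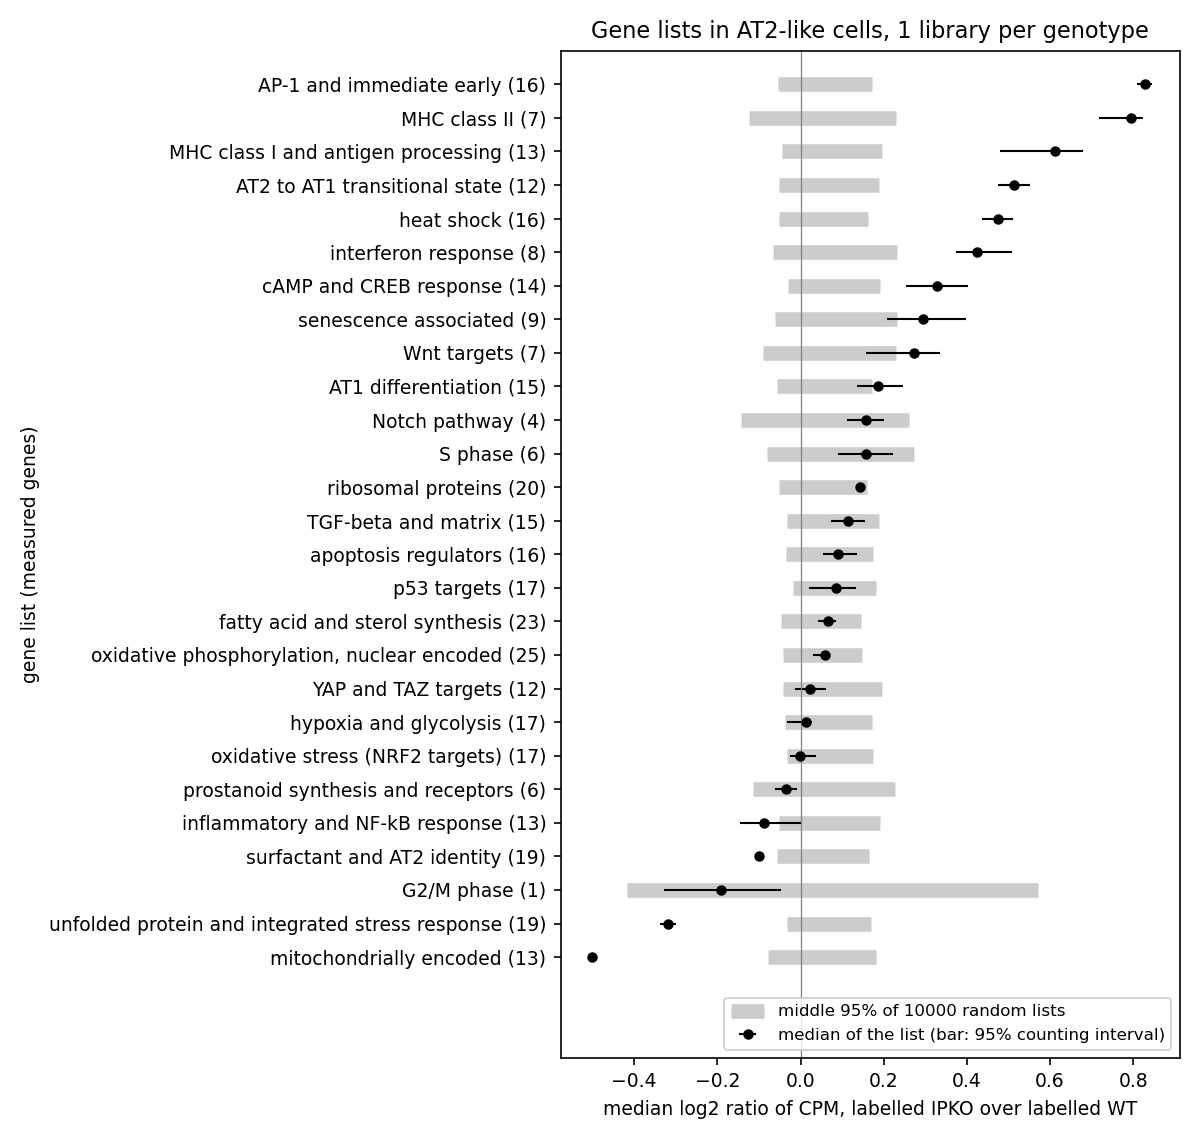
Median log2 ratio of CPM, library labelled IPKO over library labelled WT (x axis), for the 27 gene lists in AT2-like cells (y axis, with the number of measured genes); points are list medians with 95% counting intervals, and grey bars hold the middle 95% of 10000 random lists matched on expression. AP-1 genes (0.83) and MHC class II genes (0.79) stand highest and mitochondrially encoded genes (-0.50) lowest, while p53 targets (0.09) lie within the random lists.

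After each cell was thinned to 3000 UMIs, the share of AT2-like cells with a UMI of Jun was 71.7% labelled WT and 86.8% labelled IPKO, and that of Fos was 53.6% and 69.2%. For Krt8, the keratin of the transitional state, the shares were 22.4% (interval 21.3% to 23.6%) and 29.0% (27.9% to 30.1%). Without thinning the Krt8 shares were 71.1% and 77.9%, at median depths of 18655.5 and 17152 UMIs. As background, 0 of 25 thinned endothelial-like cells of each library held a Krt8 UMI. The shares for Cdkn1a were 9.35% and 10.3%, for Cd74 92.5% and 98.9%, for Scgb1a1 68.7% and 39.2%, and for the secreted antimicrobial gene Lcn2 72.8% and 64.4%. In the 25 thinned endothelial-like cells of each library the shares, labelled WT and IPKO, were 28% and 24% for Scgb1a1 and 20% and 0% for Lcn2. No background is given for Jun, Fos, Cdkn1a and Cd74, since endothelial cells express these genes themselves (Cdkn1a in 80% and 20% of the thinned cells, Jun in 100% of both).

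Within each library, transitional-like cells differed from AT2-like cells in the same way for several lists. AT1 differentiation genes were higher in transitional-like cells, with medians of 0.61 labelled WT (13 of 16 genes) and 0.84 labelled IPKO (15 of 16), led by the caveolin gene Cav1 (2.11 and 3.61) and Krt7 (1.55 and 1.99). The endothelial gene Pecam1 stood at 2.92 CPM in transitional-like and 0.40 CPM in AT2-like cells labelled IPKO, against 0.68 and 0.45 CPM labelled WT. Whether endothelial RNA adds to the Cav1 values was not tested. Fatty acid and sterol synthesis genes were lower in transitional-like cells (-0.39 labelled WT and -0.69 labelled IPKO), with Scd1 at -0.91 and -1.42. Surfactant genes had negative medians of smaller size (-0.15 and -0.30), with 5 and 9 of 19 genes lower and 1 and 2 higher. TGF-beta and matrix genes (0.46 and 0.48), MHC class II genes (0.55 and 0.38), senescence-associated genes (0.32 and 0.37) and NRF2 targets (0.29 and 0.34) had positive medians in both. Of 18 NRF2 targets, 8 were counted as higher labelled WT (none lower) and 9 labelled IPKO (1 lower). Of 10 senescence-associated genes, 5 and 6 were higher and none lower. AP-1 genes had a median of 0.85 labelled WT, where 15 of 16 were higher, and of 0.26 labelled IPKO, where 4 were higher; Jun stood at 0.82 and 0.02. This contrast between the libraries depended on the clustering, since each library clustered alone gave 0.18 and 0.35. The p53 list had medians of 0.23 (7 of 19 higher) and 0.10 (8 higher, 3 lower), with the growth factor gene Gdf15 at 1.99 and 2.55, Phlda3 at 1.58 and 1.73, and Cdkn1a at 0.99 and 1.26.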

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

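The tests of the sort and of handling for heat shock genes were chosen only after their results were seen; so were the pool without unnamed cells and the shares from each library clustered alone, without differing genes, without a mitochondrial limit and without the highest doublet scores.

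Ptgir was found in the library labelled IPKO and hardly at all in the library labelled WT, the opposite of what the labels imply. Exchanged labels would give a native pattern, predicted as at least 5 times more Ptgir in endothelial, mesenchymal and immune cells than in AT2-like cells; the observed 3.15 times (1.35 to 6.30; 2.54 with unnamed cells) falls short of that with an interval that holds 5, and rests on 8 UMIs. A transcript from the targeted allele, active in every cell, was predicted to stay within 2 times across classes: transitional-like cells had 1.34 times the AT2-like level (0.740 to 2.25) and the 3.15 times of non-epithelial cells has an interval that holds 2, so these explanations cannot be told apart with so few UMIs and an unstated deletion. Reads of neighbouring genes or free RNA were to be excluded by a median log2 ratio of nearby genes under 1, and the median of 6 genes was 0.19 (range -0.12 to 7.51), but a median was the wrong bound because 1 of the 6, Pnmal2, was itself at 7.51, so this stays open too. In barcodes that the filter removed, outside the main comparison, 9 Ptgir UMIs were found in the library labelled IPKO and 0 in the library labelled WT.

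AT2-like cells of the libraries formed separate clusters that differed in early response, heat shock and clock genes. Depth is argued against: shallower over deeper AT2-like cells within the libraries labelled WT and IPKO stood at 0.20 and 0.24 for early response genes (upper limits 0.22 and 0.26; bound 0.41), -0.021 and 0.064 for heat shock genes (0.024 and 0.097; bound 0.24) and -0.37 and -0.11 for clock genes (-0.29 and -0.0091; bound 0.72), while the median of 0.82 with thinned cells decides nothing, since thinning leaves ratios of summed counts as they are. Handling of the whole suspension was predicted to raise early response genes in endothelial-like cells by at least 0.41. They stood at -0.37 there (-0.57 to -0.22), which argues against a rise of these genes shared by both cell types. Jun was in 100% of thinned endothelial-like cells of both libraries, against 71.7% of AT2-like cells labelled WT. The cell types thus started from unlike levels, and handling that acted on AT2-like cells alone is not excluded. Heat shock genes stood at 0.57 (0.15 to 0.77) in endothelial-like cells, or 0.59 less AT2 RNA, against a bound of 0.24. For heat shock genes handling stays a candidate explanation. A different time of day at collection may account for the clock genes: in endothelial-like cells genes that peak with Arntl exceeded those that peak with Dbp by 2.62 (1.16 to 5.05), against a predicted 0.5 or more, though from few UMIs (Nr1d1 21 and 0, Dbp 2 and 2). The genotype difference that the labels name remains an open, untested explanation for all 3 groups of genes, and with 1 library each it cannot be separated from the day, the animal or the sort.

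The share of transitional-like cells was higher in the library labelled WT under the settings fixed beforehand. Joint clustering of libraries that differ is open as an explanation: with each library clustered alone, the share labelled WT was 0.479 times that labelled IPKO, so the order turned, which neither prediction (within 1.5 times, or still at least 2 times higher) had named. Loss of such cells to the mitochondrial filter cannot be told apart either, as transitional-state genes stood at 0.42 (0.24 to 0.74) in the removed barcodes, between the predicted bounds of 0 and 0.5. The list stood at 0.51 in kept AT2-like and 0.45 in kept low-RNA cells, so the value in removed barcodes does not bear on such a loss. A stricter sort of the cells labelled IPKO stays open. Cells named as the excluded types were 2.27% there (1.95% to 2.62%) and 1.45% in the library labelled WT. This test was chosen after its result was seen. The types also went different ways. T and NK cell-like cells were 1.04% labelled IPKO and 0.22% labelled WT, and endothelial-like cells 0.59% and 0.71%. Such cells do not show how the sort treated transitional-like cells. In transitional-like cells labelled WT and IPKO, Ly6a (Sca-1) stood at 4.31 and 14.8 CPM and Cd24a at 10.0 and 15.7 CPM. Pecam1 (CD31) stood at 0.68 and 2.92 CPM there, while Ptprc (CD45) had 1 and 0 UMIs and Cd34 had 0 in both. These are RNA levels and not the surface protein that the sort used, so they do not decide this. No biological explanation is drawn from a share whose order depends on the settings.

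Some lists had medians of opposite sign in different cell classes, and the difference between classes was not tested. For fatty acid synthesis genes and p53 targets, the AT2-like medians lay close to the median of all genes, 0.08. Median-of-ratios factors turned them to -0.021 and -0.0018, so no opposite direction is shown for these lists. Fatty acid and sterol synthesis genes had a median log2 ratio of -0.27 in transitional-like cells (-0.32 to -0.20) and of 0.07 in AT2-like cells. In endothelial-like cells, surfactant genes stood at 1.06 against -0.10 in AT2-like cells, beside AT2 RNA that made up an estimated 11.3% of endothelial-like UMIs labelled IPKO and 2.502% of those labelled WT. AP-1 genes stood at -0.37 in endothelial-like cells against 0.83, p53 targets at -0.72 (-1.24 to -0.14) against 0.09, and senescence-associated genes at -0.26 against 0.29. Removed barcodes of the library labelled IPKO held 132665 haemoglobin UMIs, 16 barcodes being mostly haemoglobin, and those of the library labelled WT held 188. Kept cells labelled IPKO and WT held 11546 (85.6 CPM) and 26 (0.209 CPM), and 1 kept barcode labelled IPKO was itself mostly haemoglobin. In AT2-like cells Hbb-bs stood at 412 and 10 UMIs (3.30 and 0.098 CPM). RNA of red blood cells thus also differed inside the compared cells, at a far lower level than over all kept cells.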

How the results depend on the processing

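The settings of each library clustered alone, without the 309 differing genes, without a mitochondrial limit and without the highest 8% of doublet scores were chosen only after seeing the data. No paired analysis was possible because each group holds 1 library and no result comes from a test; leaving out a replicate and other splits of the samples cannot be done either. Depth limits genes near 5 CPM and classes of few cells, such as the 48 endothelial-like cells per library. Of the list medians between the libraries, 210 values under other settings stayed within the counting interval and 128 moved beyond it. Another 12 changed sign where the counting interval of the main value left out no difference. For genes these numbers were 176, 125 and 1, and for list contrasts between states 121, 88 and 5. The values that moved include changes of sign where that interval held no difference, such as Trp53 (0.01, lowest -0.15) and Mdm2 (0.03, lowest -0.05). Of the class shares 4 stayed within the interval and 40 moved; of the shares of cells with a UMI, 18 and 78. Where no cause is shown by the setting itself, the cause was not tested.

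The share of transitional-like cells (WT 16.0%, IPKO 3.57% as labelled) became, in that order, 1.62% and 1.39% at Leiden resolution 0.3, 13.8% and 16.9% at resolution 1.0, 2.14% and 15.7% with 15 principal components, 1.85% and 20.003% with up to 10% mitochondrial UMIs, 18.4% and 11.7% with at least 1000 genes, 22.4% and 6.49% with doublets kept (3 more cells), 8.21% and 17.2% with each library clustered alone, 3.91% and 10.6% with no mitochondrial limit and 2.18% and 1.64% without the highest 8% of doublet scores. With components centred per library the share labelled WT was 4.55%, and without differing genes the share labelled IPKO was 18.0%.

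For the medians of surfactant (-0.10), transitional-state (0.51), AP-1 (0.83) and p53 (0.09) genes in AT2-like cells, the values that left the counting interval are as follows. TMM factors gave -0.18, 0.43, 0.75 and 0.0037, and turned fatty acid synthesis to -0.016 and oxidative phosphorylation to -0.024; median-of-ratios factors gave -0.19, 0.42, 0.74 and -0.0018, and turned these lists to -0.021 and -0.030. Both lower every ratio alike, by 0.08 and 0.09, which shows the cause. A total without the 20 genes with the most UMIs gave surfactant -0.15, AP-1 0.78 and p53 0.0072, and turned prostanoid genes to 0.059 and G2/M to 0.0035. All kept cells gave surfactant -0.086, transitional 0.10 and AP-1 0.63, and turned prostanoid genes to 0.090. Each library clustered alone gave -0.063, 0.054, 0.59 and 0.00083, and turned TGF-beta genes to -0.039 and Cdkn1a to -0.0022. Doublets kept gave transitional 0.34 and AP-1 0.87. Thinning and within-cell means each gave surfactant -0.11. Means over members gave surfactant -0.083, transitional 0.59 and AP-1 0.71. Members with at least 1 CPM gave transitional 0.59, prostanoid genes 0.17 and G2/M 0.056, and members with at least 20 CPM gave transitional 0.39, AP-1 0.84 and Wnt targets -0.045, where other members enter the lists.

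In contrasts of transitional-like with AT2-like cells, AP-1 (0.85 labelled WT, 0.26 labelled IPKO) became 0.18 and 0.35 with each library clustered alone, where YAP and TAZ targets (-0.028) and Wnt targets (-0.040) turned in the library labelled WT. Thinning to 3000 UMIs gave AP-1 0.13 labelled IPKO. A total without the 20 top genes gave AP-1 0.75 and p53 0.13 labelled WT, p53 -0.0127 labelled IPKO, and ribosomal protein genes -0.021 and -0.026. The share of AT2-like cells with a Krt8 UMI (22.4% and 29.0%) was 12.03% and 16.2% thinned to 1500 UMIs, 38.0% and 46.8% thinned to 6000 and 71.1% and 77.9% with no thinning, as fewer or more UMIs per cell give by construction.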

Other observations

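The clock genes and their phases were chosen only after the ratios of Nr1d1 and Nr1d2 in AT2-like cells had been seen, and the Pnmal2 test after its ratio there; its pool without unnamed cells was chosen after the wider pool had been seen.

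Many clock genes differed in AT2-like and transitional-like cells. In AT2-like cells Cry1 (log2 ratio, labelled IPKO over labelled WT, 2.28), Npas2 (1.13), Arntl (0.65) and Nfil3 (0.47), which belong to the positive arm of the clock or peak with it, were higher in the library labelled IPKO, while Nr1d1 (-4.35), Nr1d2 (-3.41), Dbp (-2.04), Tef (-0.78) and Per1 (-0.75), which peak at the opposite phase, were lower. Per2 went the other way, at 1.34, while Clock stood at 0.07 and Per3 at -0.01. The median of the Arntl-phase genes exceeded that of the Dbp-phase genes by 1.43 in AT2-like cells (1.33 to 1.59) and by 2.84 in transitional-like cells (2.47 to 3.45), where Dbp stood at -4.09.

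MHC class II genes were higher in the library labelled IPKO in each of these classes: the median was 0.79 in AT2-like, 0.57 in transitional-like and 1.26 in endothelial-like cells, the last with the AT2 RNA difference named above. Interferon response genes stood at 0.72 and heat shock genes at 0.55 in transitional-like cells. Unfolded protein response genes were lower in transitional-like cells too, at -0.37, with 11 of 19 lower and none higher. Transitional-state genes counted per cell had the same 95th percentile of 8 UMIs in both libraries after thinning, and 99th percentiles of 18 labelled WT and 16.5 labelled IPKO.

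Genes near Ptgir differed more often than genes elsewhere, and a hypothesis is that a chromosome 7 segment of another mouse strain, carried along with a targeted allele, may differ between the animals. The share of genes with a 1.5-fold difference within 10 Mb was 4.13 times that elsewhere, above the predicted 3 times. Its interval of 2.27 to 6.70 holds 3, and it treats the genes as independent, which neighbouring genes need not be. The share near Ptgir is the pattern itself and does not favour such a segment over other causes, so the hypothesis stays open. Such a segment marks the library of the targeted animal only if its strain origin is known, so it does not tell which label is right. The AP-1 median does not rest on it, as it was 0.82 over the 15 members without Fosb.

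Pnmal2 and Pnmal1 differed in the same direction as Ptgir, and another hypothesis is that transcription around a targeted allele may be altered. It predicts a like level of Pnmal2 in all classes labelled IPKO. Transitional-like cells had 0.990 times the AT2-like level, and endothelial-like, mesenchymal-like and immune cells 0.514 times (0.0620 to 1.87), from 2 UMIs. The wider pool with unnamed cells, also with 2 UMIs, stood at 1.19 CPM (0.144 to 4.30) against 3.59 CPM in AT2-like cells. That value lies just outside the predicted range, with an interval that reaches into it. The counts in these pools are too few to exclude or to favour the hypothesis. Of 501 Pnmal2 UMIs in all kept cells labelled IPKO, 448 were in AT2-like, 17 in transitional-like and 2 in the wider pool. Labelled WT, these counts were 15, 2, 0 and 2. The other UMIs lay in classes that were not compared, so a like level in all classes was not tested.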
